A study of Mus musculus with 12 samples.

How the data were processed

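The samples were luminal and basal mammary cells of wild-type FVB/N female mice, sorted by flow cytometry from virgin animals, from animals at day 18.5 of pregnancy and from animals at day 2 of lactation. The labels give 2 mice per stage and 2 libraries for each cell type and stage, so that 12 libraries form 6 groups of 2. RNA came from lysed sorted cells by a column kit and no treatment was given, per the labels. The run names in the labels put the 6 luminal libraries in lane 1 and the 6 basal libraries in lane 2. Cell type and lane therefore cannot be separated in any comparison of basal with luminal libraries.

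The deposited table holds 1 raw read count per Entrez gene identifier and library for 27179 genes, with no normalisation applied, and a length per gene that was deposited beside the counts and used only for a check of length trends. CASAVA 1.8.2, Subread 1.4.4, featureCounts and the builds GRCm38 and mm10 are named in the submitters' processing notes without a stated role. The strand setting, the rule for reads with several positions and the version of the annotation are not given in the sources used here. Overlapping genes and near-identical copies are therefore reported as uncertain. The 12 deposited files of single libraries were compared with the table and 0 counts differed. Symbols came from a RefSeq gene table of the assembly GRCm38.p6 and 25275 identifiers matched. The 1904 identifiers without a symbol held between 0.54% and 1.37% of the counts of a library and stayed in the tests. Coordinates are those of the same RefSeq table. Exon overlap with other genes was computed from GENCODE vM21 models for 194 of the 196 named genes and exceeded 20% of the exon length in 7.

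Library totals ran from 20.02 M to 24.72 M counts. Counting intervals and floors cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Genes with enough counts for a test were kept by filterByExpr with a minimum count of 10 by group, which left 15969 genes. Counts were scaled by TMM factors and compared by edgeR 4.0.16 in R 4.3.3, with a quasi-likelihood F-test on 1 fit of 6 group means over all 12 libraries. P-values were adjusted by the Benjamini-Hochberg method over the genes tested and a gene was called at an adjusted p below 0.05. Standard errors are the absolute log2 change divided by the square root of F. Levels are TMM-scaled CPM with the SD of 2 libraries, so they need not add to the same total in each library. With 2 libraries per group the spread of a single group is poorly known, and the 6 groups share 1 estimate.

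The comparisons were pregnant with virgin, lactating with pregnant and lactating with virgin within each cell type, basal with luminal at each stage and averaged over the stages, and the difference of the luminal and the basal change (luminal minus basal). The labels number the libraries 1 and 2 in every group without saying that a number marks a mouse. The deviations of same-numbered luminal and basal libraries of a stage correlated over 9096 genes at 0.249 in virgin, 0.355 in pregnant and 0.161 in lactating mice, against -0.277 to 0.164 in the other pairs of groups. The numbers were taken to pair the 2 cell types of a mouse, from the data and not from a label. In lactating mice the value (0.161) lay below the highest of the other pairs (0.164). For unrelated groups the sign depends only on how the libraries were numbered, so the size matters. The values in virgin (0.249) and lactating mice were both smaller in size than that of another pair (-0.277). The pairing is therefore only assumed in virgin and in lactating mice. A fit with the replicate block was run as an alternative.

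There were 28 gene lists with 397 entries, of which 395 matched the table. They cover milk proteins, milk fat synthesis, milk fat globule secretion, lactose synthesis, milk ion and nutrient transport, cholesterol synthesis, prolactin and STAT5 signalling, ER protein folding and stress, the BCL2 family, EGF ligands and receptors, cell cycle, oxidative phosphorylation, tight junctions, hormone-sensing luminal cells, alveolar and luminal progenitors, luminal identity, basal identity, contractile apparatus, basement membrane, circadian clock, dissociation and immediate early genes and interferon response. Marker lists of fibroblasts, endothelial cells, pericytes, leukocytes, adipocytes and erythroid cells cover other cells of the gland. Lists, comparisons, the naming rule and all alternatives but 1 were fixed before the data were examined. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 on log2 CPM (prior count 2), which compares its genes with all others, and adjusted over 336 list tests. The same test with an estimated correlation and fry, which tests the direction of the list itself, stand beside it. Camera called 147 of the 336 list tests, of which 0 held with an estimated correlation and 142 were kept by fry in the same direction.

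Genes were named by rule in the 4 comparisons of neighbouring stages, in the averaged comparison of cell types and in the difference of the changes from pregnancy to lactation. The rule took the 5 called genes with the highest and the 5 with the lowest log2 change, among those with a mean of at least 10 CPM in the higher group and libraries that did not overlap. For the difference of changes that mean could be in any group, and libraries could overlap. In each comparison the rule added, for the 8 lists with the smallest camera p, the 3 called members with the lowest adjusted p in the direction of the list and 1 called member against it. Called members of a list with 3 or fewer, Mcl1 in every comparison, and called BCL2 family and EGF genes in luminal lactating against pregnant cells completed it. Many of the genes so named whose call ended without 1 library are left out of the text, which is a choice made after their values were seen. A few other genes named by the rule are not reported here. A ratio against a group at 0 counts was set against a floor of 3 counts over the group.

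The alternatives were RLE normalization, library size without composition factors, no filter on low counts, a filter of 1 CPM in at least 4 libraries, DESeq2 1.42.0, limma voom, library sizes without the milk protein list and the 20 most abundant genes, the replicate block, a fit of 1 cell type alone, and each of the 12 libraries left out. A subtraction of luminal carry-over from the basal libraries was added after seeing the data. It took the median ratio of 8 milk transcripts in basal to luminal libraries of the stage as the luminal share.

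The tests were tested on simulated data drawn from the real dispersions and library sizes and from partly altered real means. In the tests of genes and lists the luminal lactating means were replaced by those of luminal pregnancy. For the difference these were also moved by the basal change. Only the chosen genes were then changed, so the luminal rise of milk transcripts to lactation was absent and the rates do not cover it. For luminal lactating against pregnant cells (15793 genes), edgeR recovered 32.8% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 6.8% false among 148 calls. For the difference of the changes from pregnancy to lactation (15803 genes) it recovered 10.4% of 67 genes, 45.5% of 66 and 78.8% of 66 at the same fold sizes, with 6.3% false among 95 calls. In a further simulation of luminal lactating against pregnant cells, camera called 10 of 10 changed lists and 0 of 10 unchanged ones. It did so both with the preset and with the estimated correlation. Simulated genes were drawn independently of each other, so this cannot tell which correlation suits real lists. A luminal share of 3% put into simulated basal libraries was estimated at 2.57% to 3.38%. The milk transcripts that define the share were first set to 0 in the basal means. The estimate was thus not tested for basal cells that make these transcripts.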

Results

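RNA sequencing counted the reads of each gene in luminal cells, the inner layer of the mammary epithelium that makes milk and senses hormones, and in basal cells, the outer layer that holds the contractile myoepithelium. Cells of both types came from virgin mice, from mice late in pregnancy (day 18.5) and from mice early in lactation (day 2), with 2 libraries for each of the 6 groups. The luminal libraries held 20.39 M and 21.71 M counts in virgin, 22.24 M and 21.99 M in pregnant and 24.72 M and 24.66 M in lactating mice. The basal libraries held 23.23 M and 21.78 M, 24.10 M and 22.67 M, and 21.53 M and 20.02 M at the same stages. Between 16701 and 18533 genes had at least 1 count in a library. Replicate libraries correlated at 0.9887 to 0.9921 (Pearson, log2 CPM across genes, which are not independent replicates). The first principal component of the 2000 most variable genes held 80.3% of their variance and parted luminal from basal libraries, and the second held 11.1% and ordered the stages within each cell type.

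Milk protein transcripts took a growing part of the luminal libraries. The 13 genes of that list held 1.505% and 1.525% of the counts in virgin, 19.2% and 22.1% in pregnant and 51.3% and 49.9% in lactating luminal libraries. In basal libraries they held 0.047% and 0.061%, then 0.759% and 0.518%, then 0.580% and 0.571%. Csn1s2a, an alpha-casein gene, alone made up 11.7% and 11.4% of the counts of lactating luminal cells. Scaling by library size alone, in which these reads count in full, lowered the other luminal genes. It moved the median log2 change of all genes by -0.504 in luminal pregnant against virgin cells, by -0.851 in luminal lactating against pregnant cells and by -1.36 in luminal lactating against virgin cells. The shift was -0.156 for basal pregnant against virgin and -0.203 for basal lactating against virgin cells. Between cell types it was -0.156 in virgin, 0.189 in pregnant and 0.993 in lactating mice and 0.341 on average, and -0.343 and -0.793 for the differences of the pregnancy and lactation changes. Changes below are relative to the TMM-scaled median gene. Every level is a TMM-scaled CPM given as mean ± SD over 2 libraries, and every change is a log2 change with its SE from the edgeR fit.

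**Figure D1:**
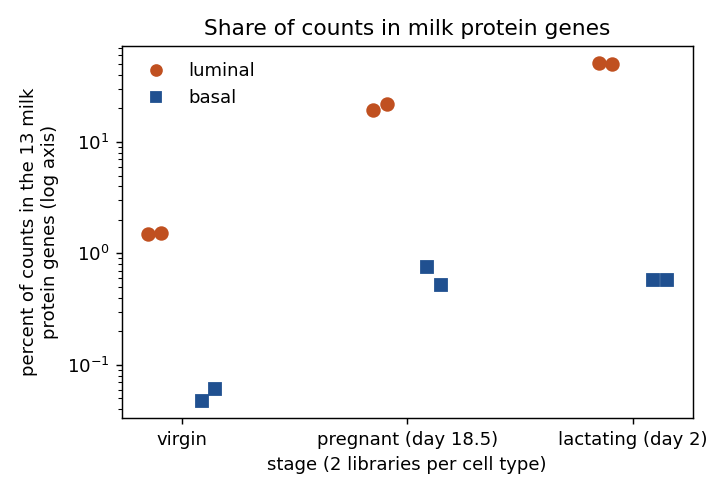
Percent of all counts in the 13 milk protein genes (log axis) for each of the 12 libraries, by cell type and stage, with 2 points per group. Luminal libraries run from 1.505% in virgin to 51.3% in lactating mice, and basal libraries from 0.047% to 0.759%.

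The first comparison asked how luminal cells differed between late pregnancy and the virgin state. Genes for milk proteins and milk fat already stood high in pregnancy. Csn1s2a went from 480 ± 54 to 59300 ± 8600 CPM, a rise of 6.95 (SE 0.33). Glycam1 (Entrez 14663; chromosome 15, 103562759 to 103565081 in GRCm38.p6), which encodes a mucin-type glycoprotein of milk, rose by 8.34 (SE 0.29), and Fabp3, a fatty acid-binding protein, rose by 8.29 (SE 0.24) from 2.74 ± 0.42 CPM. Hephl1, a multicopper oxidase, rose by 8.16 (SE 0.30) and the connexin gene Gjb6 by 7.55 (SE 0.21). Rgs8, a regulator of G-protein signalling with 2 counts in virgin libraries, was 904-fold higher (95% counting interval 250 to 7480), and its fitted change of 9.62 was 8.75 without luminal virgin replicate 1 and 12.47 without replicate 2. Genes of hormone-sensing cells stood low. The progesterone receptor gene Pgr (Entrez 18667) fell by 3.84 (SE 0.19) from 92.5 ± 28 to 6.46 ± 0.49 CPM. Foxa1, a transcription factor of oestrogen-responsive cells, fell by 3.37 (SE 0.14), and the transcriptional co-regulator Cited1 fell by 4.72 (SE 0.15).

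Of the 13 milk protein genes 12 rose, 12 also when adjusted over the list alone, with a median of 2.99 (camera adjusted p = 2.77e-09; adjusted p = 0.252 with an estimated correlation). Milk fat synthesis had 19 of 21 genes higher and 2 lower, the same when adjusted over the list alone, with a median of 1.73 (camera adjusted p = 7.01e-09; adjusted p = 0.246 with an estimated correlation). Lpl, the lipase that frees fatty acids from lipoproteins, rose by 5.87 (SE 0.23) and Thrsp, a regulator of fat synthesis, by 6.90 (SE 0.37; 7.60 without luminal virgin replicate 2), whereas Dgat2, which makes triglycerides, fell by 2.95 (SE 0.14). In milk fat globule secretion 6 of 7 genes rose, 6 over the list alone, with a median of 1.77 (camera adjusted p = 0.00114; adjusted p = 0.321 with an estimated correlation). The lipid droplet gene Plin2 rose by 3.69 (SE 0.29) and Xdh, a component of the globule membrane, by 2.65 (SE 0.26). Milk ion and nutrient transport had 9 of 11 genes higher and 1 lower, as over the list alone, with a median of 1.92 (camera adjusted p = 3.97e-05; adjusted p = 0.219 with an estimated correlation). Among them the zinc transporter Slc30a2 rose by 2.95 (SE 0.16) and the phosphate transporter Slc34a2 by 2.86 (SE 0.19). Lactose synthesis had 7 of 9 genes higher, 7 over the list alone, with a median of 0.49 that was -0.02 with library size only (camera adjusted p = 0.00248; adjusted p = 0.247 with an estimated correlation). B4galt1, the catalytic part of lactose synthase, rose by 1.90 (SE 0.18).

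Oxidative phosphorylation had 20 of 25 genes higher, 21 over the list alone, with a median of 0.47 that was -0.03 with library size only (camera adjusted p = 8.72e-07; adjusted p = 0.367 with an estimated correlation). Cox4i1 rose by 0.87 (SE 0.11). Hormone-sensing luminal genes fell in 9 of 11 cases, 10 over the list alone, with a median of -3.38 (camera adjusted p = 7.08e-07; adjusted p = 0.219 with an estimated correlation). Endothelial markers moved in the same libraries: 12 of 13 fell, 13 over the list alone, with a median of -1.87 (camera adjusted p = 4.55e-05; adjusted p = 0.499 with an estimated correlation). Pecam1 went from 23.1 ± 7.8 to 5.39 ± 0.23 CPM. Dissociation and immediate early genes had 11 of 17 lower and 2 higher, as over the list alone (camera adjusted p = 0.0218; adjusted p = 0.681 with an estimated correlation). Without luminal pregnant replicate 1 that adjusted p was 0.107, in a range of 0.00551 to 0.107 over the other settings. Tight junctions had 7 of 12 genes higher, 8 over the list alone, with a median of 0.43 that was -0.08 with library size only (camera adjusted p = 0.0268; adjusted p = 0.501 with an estimated correlation). Their camera adjusted p was 0.0641 without luminal virgin replicate 1, 0.071 without luminal pregnant replicate 2, 0.0631 with library size only and 0.118 with luminal carry-over subtracted (same median, larger SE), in a range from 0.0115. ER protein folding had 6 of 18 genes higher, 6 over the list alone, with a median of 0.25 that was -0.25 with library size only (camera adjusted p = 0.0333; adjusted p = 0.642 with an estimated correlation). That adjusted p was 0.0745 without luminal virgin replicate 1, 0.244 without luminal pregnant replicate 1 and 0.102 with library size only, in a range from 0.00127.

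The cell cycle list did not pass in this comparison: 4 of 30 genes fell, 3 over the list alone (camera adjusted p = 0.108), except that it passed without luminal pregnant replicate 1 (adjusted p = 7.21e-05, in a range up to 0.8 over the settings). Cholesterol synthesis was split, with 7 genes higher and 6 lower of 24 (median 0.06, camera adjusted p = 0.642). Prolactin and STAT5 signalling had 2 of 9 genes higher and 5 lower, the same over the list alone (median -0.52, camera adjusted p = 0.631). The BCL2 family had 3 of 16 genes higher and 5 lower and the EGF ligands and receptors 2 of 12 higher and 5 lower, with camera adjusted p = 0.689 and 0.441. Among the lowest changes, Fgb, a fibrinogen gene, fell by 9.44 (SE 0.35) from 85.4 ± 17 CPM. Nrxn3 was at least 144-fold lower in pregnancy and Pcdhac2, whose exons overlap other genes by 48.6% and which is therefore uncertain, at least 181-fold lower. Ido1, which degrades tryptophan, was 842-fold lower (95% counting interval 151 to 33300) over 1 count; its fitted change of -9.40 was -8.58 without luminal virgin replicate 2 and -8.48 and -11.84 without luminal pregnant replicates 1 and 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7335 of 15969 genes were called, 3488 higher and 3847 lower in pregnancy. With library size only 9638 were called, 1212 higher and 8426 lower.

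The series title sets lactating against pregnant glands, and the next comparison asked what changed in luminal cells between day 18.5 of pregnancy and day 2 of lactation. Csn1s2b (Entrez 12992), another alpha-casein gene, went from 18.4 ± 6.4 to 6900 ± 69 CPM, a rise of 8.55 (SE 0.28), though reads of the casein paralogs Csn1s2a and Csn1s2b may have been split between them. Atp2b2, the calcium pump that moves calcium into milk, rose by 7.37 (SE 0.23) to 586 ± 110 CPM. Egf (Entrez 13645; chromosome 3, 129677574 to 129755322), a growth factor found in milk, rose by 5.36 (SE 0.16) from 1.99 ± 0.40 to 81.3 ± 0.18 CPM. Mcl1 (Entrez 17210; chromosome 3, 95656944 to 95663179), which protects cells from apoptosis and whose name the library labels carry, fell by 0.74 (SE 0.13; edgeR adjusted p = 0.000398) from 1070 ± 110 to 645 ± 81 CPM. Cldn4 (Entrez 12740; chromosome 5, 134945123 to 134946934), a claudin of tight junctions, fell by 3.16 (SE 0.24) from 3180 ± 830 to 356 ± 120 CPM. The proliferation gene Mki67 (Entrez 17345) rose by 2.32 (SE 0.19) from 67.8 ± 17 to 338 ± 29 CPM.

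Cholesterol synthesis had 22 of 24 genes higher, 22 over the list alone, with a median of 1.77 (camera adjusted p = 1.24e-10; adjusted p = 0.252 with an estimated correlation). Insig1, which restrains sterol synthesis, rose by 4.11 (SE 0.22), and the pathway enzymes Pmvk and Tm7sf2 rose by 2.68 (SE 0.11) and 2.67 (SE 0.15). Milk fat synthesis rose in 20 of 21 genes, 20 over the list alone, with a median of 2.11 (camera adjusted p = 8.95e-10; adjusted p = 0.224 with an estimated correlation). The citrate carrier Slc25a1 rose by 4.13 (SE 0.14), the elongase Elovl5 by 2.86 (SE 0.11) and Acss2, which activates acetate, by 2.55 (SE 0.13). Milk proteins rose in 11 of 13 genes, 12 over the list alone, with a median of 2.27 (camera adjusted p = 1.83e-06; adjusted p = 0.270 with an estimated correlation). Milk fat globule secretion had 6 genes higher and 1 lower of 7, as over the list alone (median 2.06, camera adjusted p = 0.00164; adjusted p = 0.330 with an estimated correlation). Cidea, which enlarges lipid droplets, rose by 4.80 (SE 0.24) and Muc1 by 2.76 (SE 0.18), whereas Plin2 fell by 1.12 (SE 0.26). Milk ion and nutrient transport had 9 of 11 genes higher and 1 lower, as over the list alone (median 0.93, camera adjusted p = 0.00106; adjusted p = 0.224 with an estimated correlation). Slc34a2 rose by 4.18 (SE 0.20). Lactose synthesis had 4 of 9 genes higher, 4 over the list alone, with a median of 0.35 that was -0.49 with library size only (camera adjusted p = 0.0291, and 0.0866 with library size only, where it was highest; adjusted p = 0.270 with an estimated correlation).

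Cell cycle genes rose in 23 of 30 cases, 23 over the list alone, with a median of 1.05 (camera adjusted p = 4.24e-06; adjusted p = 0.549 with an estimated correlation). The median was 0.19 with library size only, with 7 genes higher and 3 lower. Rrm2, a subunit of ribonucleotide reductase, rose by 1.86 (SE 0.19) and the cyclin gene Ccna2 rose 3.49-fold. Oxidative phosphorylation rose in 22 of 25 genes, 22 over the list alone, with a median of 0.50 that was -0.36 with library size only (camera adjusted p = 2.01e-06, and 0.84 with library size only, where it was highest; adjusted p = 0.371 with an estimated correlation). ER protein folding had 9 of 18 genes higher and 1 lower, as over the list alone, with a median of 0.41 that was -0.45 with library size only (camera adjusted p = 0.0104; adjusted p = 0.589 with an estimated correlation). That adjusted p was 0.0566 without luminal pregnant replicate 2 and 0.144 with library size only, in a range from 0.000584. Tight junctions fell in 10 of 12 genes and rose in 1, with 11 lower over the list alone (median -1.04, camera adjusted p = 0.00119; adjusted p = 0.330 with an estimated correlation). Cldn3 fell by 2.26 (SE 0.15) and Marveld2 by 1.47 (SE 0.12), and Cldn8 rose by 1.64 (SE 0.19). Luminal identity, which shares Cldn3, Cldn4 and Cldn7 with that list, had 8 of 11 genes lower, 9 over the list alone (median -1.24, camera adjusted p = 0.00219; adjusted p = 0.371 with an estimated correlation).

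In the BCL2 family 8 of 16 genes fell and 1 rose, the same over the list alone, with a median of -0.68 (camera adjusted p = 0.0476; adjusted p = 0.501 with an estimated correlation). The survival gene Bcl2l1 (Entrez 12048), which encodes BCL-XL, fell by 2.49 (SE 0.16) from 260 ± 23 to 46.3 ± 7.7 CPM, and Bcl2 fell by 1.84 (SE 0.26). Genes that promote apoptosis fell too. Bik fell by 1.83 (SE 0.22), Bbc3, which encodes PUMA, by 1.58 (SE 0.22), Bcl2l11, which encodes BIM, by 1.31 (SE 0.14) and Bax by 0.65 (SE 0.13). Bcl2l2, a survival gene, rose by 1.48 (SE 0.11) from 46.7 ± 1.9 to 130 ± 2.4 CPM. The call of the whole list was fragile. Its camera adjusted p was 0.0586 without luminal pregnant replicate 2, 0.0679 without luminal lactating replicate 2, 0.0573 and 0.0549 without basal virgin replicates 1 and 2, 0.144 with library size only, 0.0614 with luminal carry-over subtracted (same median) and 0.052 with the replicate block, in a range from 0.031. Of 12 EGF ligands and receptors 8 fell and 1, Egf, rose, the same over the list alone (median -0.97, camera adjusted p = 0.035; adjusted p = 0.501 with an estimated correlation). That adjusted p was 0.0748 without luminal pregnant replicate 2, 0.0558 without luminal lactating replicate 2, 0.0631 with luminal carry-over subtracted (same median) and 0.436 with library size only, in a range from 0.0205. The ligand genes Hbegf and Tgfa fell by 1.85 (SE 0.22) and 1.29 (SE 0.29), and the receptor genes Erbb3, Egfr and Erbb2 by 1.42 (SE 0.16), 0.99 (SE 0.15) and 0.91 (SE 0.11). Areg, an EGF ligand of hormone-sensing cells, fell by 2.53 (SE 0.37), or by 1.91 without luminal pregnant replicate 1.

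**Figure D2:**
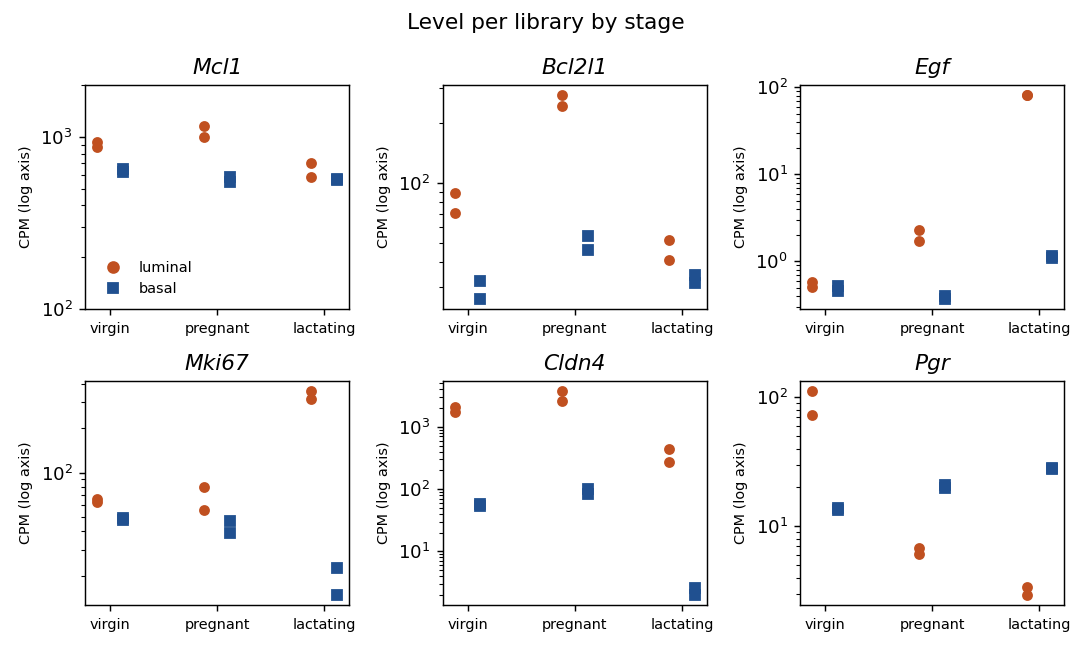
TMM-scaled CPM (log axis) of Mcl1, Bcl2l1, Egf, Mki67, Cldn4 and Pgr in each of the 12 libraries, by cell type and stage, with 2 points per group. In luminal cells Egf went from 1.99 ± 0.40 CPM in pregnancy to 81.3 ± 0.18 in lactation and Bcl2l1 from 260 ± 23 to 46.3 ± 7.7 (mean ± SD, n = 2).

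Prolactin and STAT5 signalling had 6 of 9 genes higher and 2 lower, 7 and 2 over the list alone (median 0.72, camera adjusted p = 0.107). Hormone-sensing genes had 5 of 11 higher and 4 lower, with a median of 0.43, a mean of -0.14 and a camera test pointing up (adjusted p = 0.484). That list passed with library size only (adjusted p = 0.0366, the lowest of the settings), with a median of -0.43. Interferon response had 3 of 15 genes higher and 2 lower (median 0.44, camera adjusted p = 0.167). Among markers of other cells, fibroblast genes had 4 of 11 higher (median 0.69, camera adjusted p = 0.0594, in a range of 0.0156 to 0.173 over the settings), pericyte genes 0 of 6 called (median 0.88, camera adjusted p = 0.244), and leukocyte genes 1 of 11 higher and 2 lower (median -1.42, camera adjusted p = 0.29). Of 5 erythroid genes 3 fell (median -1.08, or -1.84 without a gene at 0 counts in a group; camera adjusted p = 0.286). Rspo1, a secreted activator of WNT signalling, fell by 6.52 (SE 0.36) from 338 ± 91 to 3.69 ± 0.18 CPM, and Ccn2, a matricellular protein gene whose exons overlap another gene by 23.2% and which is uncertain for that reason, fell by 6.99 (SE 0.32). The lipocalin gene Apod rose by 7.06 (SE 0.38) to 60.1 ± 22 CPM. The imprinted RNA H19 was 88.6-fold lower (95% counting interval 30.1 to 431) over 3 counts; its fitted change of -6.42 was -10.94 and -5.42 without luminal lactating replicates 1 and 2. The edgeR test called 7716 genes at an adjusted p below 0.05, 3781 higher and 3935 lower in lactation. With library size only 10597 were called, 1013 higher and 9584 lower.

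Lactating luminal cells were also set against virgin ones, which spans both steps. All 13 milk protein genes rose, 13 over the list alone, with a median of 5.41 (camera adjusted p = 6.04e-10; adjusted p = 0.252 with an estimated correlation). Milk fat synthesis had 20 of 21 genes higher and 1 lower, as over the list alone (median 4.25, camera adjusted p = 1.59e-11; adjusted p = 0.224 with an estimated correlation). Oxidative phosphorylation had 24 of 25 higher, 25 over the list alone, with a median of 0.89 that was -0.47 with library size only (camera adjusted p = 5.46e-10; adjusted p = 0.270 with an estimated correlation). Hormone-sensing genes had 9 of 11 lower, 9 over the list alone (median -3.57, camera adjusted p = 0.000581; adjusted p = 0.224 with an estimated correlation). Endothelial markers had 10 of 13 lower, 11 over the list alone (median -1.63, camera adjusted p = 0.0122; adjusted p = 0.642 with an estimated correlation). Mcl1 fell by 0.48 (SE 0.13; edgeR adjusted p = 0.00515), a call lost without luminal lactating replicate 2 (change -0.33, adjusted p = 0.095, the only setting of those run that ended it). By edgeR 9609 genes were called, 4263 higher and 5346 lower, and with library size only 13427, 931 higher and 12496 lower.

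The next comparison asked how basal cells differed between late pregnancy and the virgin state. Contractile genes stood higher in pregnancy: Actg2 (Entrez 11468), a smooth muscle actin, went from 106 ± 12 to 663 ± 130 CPM, a rise of 2.64 (SE 0.17), and Mylk (Entrez 107589), the kinase that starts smooth muscle contraction, from 737 ± 50 to 3410 ± 470 CPM, a rise of 2.21 (SE 0.18). Lgr5, a receptor gene of stem cells in several epithelia, fell by 3.97 (SE 0.30) from 103 ± 36 to 6.60 ± 2.1 CPM, and the semaphorin gene Sema3b fell by 4.15 (SE 0.26). Wnt4, a WNT ligand, rose by 2.01 (SE 0.22) in basal cells, or by 2.65 with luminal carry-over subtracted. The serpin gene Serpinb11 fell by 7.26 (SE 0.32), or by 7.96 without basal pregnant replicate 1, and the thioesterase gene Them5 fell by 3.95 (SE 0.27). The 5 highest changes included milk transcripts. The median ratio of 8 milk transcripts to their luminal level was 3.54% and 2.58% in the 2 basal libraries of pregnancy. It was 1.27% and 2.24% in virgin and 1.19% and 1.16% in lactating basal libraries, each against luminal libraries of the same stage. Csn1s2a rose by 7.63 (SE 0.35) to 1510 ± 420 CPM and Wap, a whey protein gene, by 7.17 (SE 0.42). Glycam1 rose by 7.16 (SE 0.29). These 3 genes are among the 8 that define the luminal share. Its subtraction left 0 counts of Csn1s2a and Wap in virgin basal libraries and turned Glycam1 to -1.55, which is no test of their rises. Pigr, which carries antibodies across epithelia and is not among those 8 genes, rose by 5.62 (SE 0.39). It kept its call with luminal carry-over subtracted, which left 30.6% of its counts in pregnancy and 9 of 30 counts in virgin libraries. What is left depends on the estimated luminal share, so this rise is not assigned to basal cells.

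The contractile list had 15 of 18 genes higher and 1 lower, with 15 and 2 over the list alone, and a median of 1.42 (camera adjusted p = 6.1e-07; adjusted p = 0.330 with an estimated correlation). Pgm5, a protein of muscle cell adhesions, rose by 2.58 (SE 0.16). Oxidative phosphorylation rose in 24 of 25 genes, 24 over the list alone, with a median of 0.51 (camera adjusted p = 1.86e-10; adjusted p = 0.270 with an estimated correlation). Sdhc rose by 0.80 (SE 0.09) and Ndufa4 by 0.75 (SE 0.11). Basement membrane had 5 of 11 genes higher and 1 lower, as over the list alone (median 0.61, camera adjusted p = 0.0144; adjusted p = 0.367 with an estimated correlation). Cell cycle had 8 of 30 genes lower, 8 over the list alone, with a median of -0.39 (camera adjusted p = 0.0054; adjusted p = 0.699 with an estimated correlation). Pcna, a DNA replication clamp, fell by 0.72 (SE 0.15) and the cyclin gene Ccne1 by 0.99 (SE 0.20). Without basal pregnant replicate 2 that adjusted p was 0.0668, in a range from 0.000483. Dissociation and immediate early genes had 12 of 17 lower, against 13 lower and 1 higher over the list alone (median -0.65, camera adjusted p = 0.000161; adjusted p = 0.501 with an estimated correlation). Atf3 fell by 1.64 (SE 0.20). Endothelial markers moved with them: 12 of 13 fell, 12 over the list alone, with a median of -1.46 (camera adjusted p = 2.98e-06; adjusted p = 0.416 with an estimated correlation). Pecam1 went from 103 ± 35 to 28.0 ± 7.3 CPM.

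Lists of luminal character also moved in basal libraries. Milk proteins had 12 of 13 genes higher, 12 higher and 1 lower over the list alone (median 2.96, camera adjusted p = 1.64e-11; adjusted p = 0.252 with an estimated correlation). Milk fat globule secretion had 4 of 7 higher, 4 over the list alone (median 1.75, camera adjusted p = 0.00349; adjusted p = 0.359 with an estimated correlation). Milk fat synthesis had 8 of 21 higher and 1 lower, 8 and 3 over the list alone (median 0.21, camera adjusted p = 0.0166; adjusted p = 0.487 with an estimated correlation). Hormone-sensing genes had 6 of 11 lower and 2 higher, 7 and 2 over the list alone (median -1.92, camera adjusted p = 0.00736; adjusted p = 0.252 with an estimated correlation). With luminal carry-over subtracted, the highest camera adjusted p over the settings was reached for each: 0.726 for milk proteins, 0.519 for milk fat synthesis, 0.301 for globule secretion and 0.729 for hormone-sensing genes. For milk proteins this follows from the method, since 8 of the 13 genes define the share. The median of milk fat synthesis hardly moved (0.21 to 0.19; quartiles -0.21 to 1.34 before and -0.42 to 0.69 after), and its call ended as 6 genes were then higher and 4 lower. Globule secretion went from 1.75 (quartiles 0.30 to 2.06) to 0.46 (-0.14 to 1.23) and hormone-sensing genes from -1.92 (-2.24 to -0.37) to -0.71 (-2.02 to 0.59). Milk ion and nutrient transport did not pass (2 of 11 higher, median 0.05, camera adjusted p = 0.721).

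Adipocyte markers had 3 of 5 tested genes higher (median 3.04, camera adjusted p = 0.0682). Plin4, a coat protein of fat droplets, rose by 4.05 (SE 0.32), or by 4.77 without basal virgin replicate 2, and went from 9.01 ± 5.1 to 149 ± 18 CPM. The list passed with library size only (adjusted p = 0.0178), without basal virgin replicate 2 (0.0376) and without basal pregnant replicate 1 (0.0206). Erythroid markers had 3 of 5 genes lower (median -2.00, camera adjusted p = 0.0941), pericyte markers 1 of 6 higher and 1 lower (median 0.13, camera adjusted p = 0.937) and interferon response 1 of 15 higher and 2 lower (median -0.03, camera adjusted p = 0.765). The circadian clock had 6 of 16 genes higher and 1 lower (median 0.28, camera adjusted p = 0.169, but 0.0477 without basal virgin replicate 2 and 0.0316 without basal pregnant replicate 2). Mcl1 was not called (change -0.17, SE 0.13, edgeR adjusted p = 0.341). The edgeR test called 4794 genes, 2491 higher and 2303 lower in pregnancy, and 3009 without basal pregnant replicate 2. With library size only it called 5133, 1647 higher and 3486 lower.

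In the step from pregnancy to lactation the question was which changes basal cells shared with luminal cells and which ran the other way. Cell cycle genes fell in basal cells: Ccna2 fell by 2.16 (SE 0.23) from 9.95 ± 0.85 to 2.22 ± 0.04 CPM, Rrm2 fell by 1.81 (SE 0.19) and the mitotic motor gene Kif11 by 2.26 (SE 0.24). Among genes of tight junctions Cldn4 fell by 5.32 (SE 0.30) from 91.7 ± 11 to 2.29 ± 0.38 CPM in basal libraries, and Ocln by 3.52 (SE 0.30), over 12 counts in lactation. Most of these counts may be luminal. Subtracting luminal carry-over left 7.6% of the Cldn4 counts in pregnancy and 7.9% in lactation, and 17.7% and 8.3% of those of Ocln. The counts left still fell, from 359 to 8 for Cldn4 and from 29 to 1 for Ocln. Such small remainders depend on the estimated luminal share, so neither fall can be assigned to basal cells. Lif, a cytokine of the interleukin 6 family, fell by 3.71 (SE 0.26) and the complement gene C3 by 4.04 (SE 0.36). Krt5 (Entrez 110308), a keratin of basal cells, rose by 0.87 (SE 0.15) from 1950 ± 260 to 3560 ± 490 CPM and Col17a1, a collagen of hemidesmosomes, by 1.08 (SE 0.16). Mrgprf, an orphan receptor gene, rose by 5.15 (SE 0.28) from 1.06 ± 0.25 to 37.6 ± 3.3 CPM, the peptide hormone gene Cck by 4.01 (SE 0.35), and Tnni2, a troponin gene, by 5.75 (SE 0.32), or by 6.42 without basal pregnant replicate 2. Sync, whose exons overlap another gene by 27.3% and which is uncertain for that reason, rose by 3.66 (SE 0.38).

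Of 30 cell cycle genes 26 fell, 27 over the list alone, with a median of -1.89 (camera adjusted p = 4.26e-12; adjusted p = 0.367 with an estimated correlation). Cholesterol synthesis had 19 of 24 genes higher, 21 over the list alone, with a median of 1.18 (camera adjusted p = 8.16e-11; adjusted p = 0.252 with an estimated correlation). The enzyme gene Msmo1 rose by 2.04 (SE 0.17). Oxidative phosphorylation fell in 19 of 25 genes, 20 over the list alone (median -0.44, camera adjusted p = 7.87e-08; adjusted p = 0.330 with an estimated correlation). Atp5b fell by 0.75 (SE 0.12). Tight junctions had 10 of 12 genes lower and 1 higher, as over the list alone (median -2.31, camera adjusted p = 3.58e-07; adjusted p = 0.252 with an estimated correlation). With luminal carry-over subtracted the median was -1.05, with 7 genes lower and 1 higher (adjusted p = 0.00832), and Cldn3 went from -2.33 to -0.64 (adjusted p = 0.295). In pregnancy 9 of the 12 genes kept less than 50% of their basal counts, so much of this fall may be luminal. Basal identity had 8 of 16 genes higher and 1 lower, as over the list alone (median 0.60, camera adjusted p = 0.0154; adjusted p = 0.487 with an estimated correlation). Snai2, a transcription factor of basal cells, fell by 0.74 (SE 0.15). The contractile list had 5 of 18 genes higher, 5 over the list alone (median 0.40, camera adjusted p = 0.0246; adjusted p = 0.639 with an estimated correlation). That call ended without basal pregnant replicate 1 (adjusted p = 0.187) and without basal lactating replicate 1 (0.0746), in a range from 0.00219. Immediate early genes had 10 of 17 higher, 10 over the list alone (median 0.62, camera adjusted p = 0.000247; adjusted p = 0.501 with an estimated correlation). Atf3 rose by 1.88 (SE 0.20) and Fosb by 1.09 (SE 0.22).

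Alveolar and luminal progenitor genes fell in 6 of 7 cases, 6 over the list alone (median -1.66, camera adjusted p = 0.000581; adjusted p = 0.270 with an estimated correlation). Cd14 fell by 1.66 (SE 0.22). That adjusted p was 0.11 with luminal carry-over subtracted, the highest of the settings. The median then was -1.48 (quartiles -2.91 to -1.10 before and -2.08 to 0.09 after), and 3 of the 7 genes were called lower. The median SE of the genes rose from 0.24 to 0.42. The subtraction left a median of 51.7% of the basal counts of these genes in pregnancy and 84.8% in lactation. Part of this fall may therefore be luminal. Leukocyte markers had 8 of 11 tested genes lower and 1 higher, as over the list alone (median -2.77, or -2.74 without a gene at 0 counts in a group; camera adjusted p = 0.00592; adjusted p = 0.392 with an estimated correlation). Lyz2 fell by 2.71 (SE 0.40) from 5.10 ± 1.5 to 0.770 ± 0.18 CPM. The circadian clock had 2 of 16 genes higher and 6 lower (median -0.64, camera adjusted p = 0.0621, but 0.0477 without basal virgin replicate 2 and 0.0136 without basal pregnant replicate 2). Milk proteins had 4 genes higher and 3 lower of 13, with a median of -0.09, a mean of 0.40 and a camera test pointing up (adjusted p = 0.71). ER protein folding had 2 of 18 higher and 5 lower (median -0.33, camera adjusted p = 0.067, but 0.0277 without basal pregnant replicate 2). Mcl1 stood at 566 ± 29 and 568 ± 4.5 CPM (edgeR adjusted p = 0.99). By edgeR 5287 genes were called, 2508 higher and 2779 lower in lactation, but 2735 without basal pregnant replicate 1 and 2806 without basal lactating replicate 2.

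**Figure D3:**
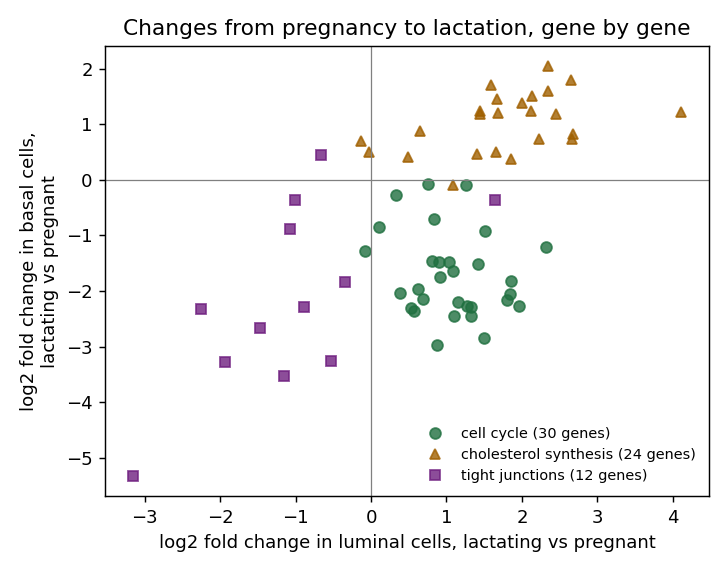
Log2 change from pregnancy to lactation in luminal (horizontal axis) and basal cells (vertical axis) for the genes of the cell cycle, cholesterol synthesis and tight junction lists, 1 point per gene, from the edgeR fit of 12 libraries. Cell cycle genes lie to the lower right (medians 1.05 and -1.89), cholesterol genes to the upper right (1.77 and 1.18) and tight junction genes to the lower left (-1.04 and -2.31, the latter -1.05 with luminal carry-over subtracted); none of these 6 medians changed sign under a scaling alternative.

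Lactating basal cells were also set against virgin ones. Cell cycle genes had 29 of 30 lower, 29 over the list alone (median -2.20, camera adjusted p = 5.29e-12; adjusted p = 0.371 with an estimated correlation). The contractile list had 16 of 18 genes higher and 2 lower, as over the list alone (median 1.97, camera adjusted p = 6.18e-07; adjusted p = 0.330 with an estimated correlation). ER protein folding had 12 of 18 lower and 1 higher, with 13 lower over the list alone (median -0.61, camera adjusted p = 0.00527; adjusted p = 0.553 with an estimated correlation). Endothelial markers had 10 of 13 lower, 11 over the list alone (median -1.49, camera adjusted p = 0.000522; adjusted p = 0.528 with an estimated correlation). Mcl1 was not called (change -0.16, SE 0.13, edgeR adjusted p = 0.308), but was with library size only (-0.37, adjusted p = 0.0236, the lowest of the settings). By edgeR 7579 genes were called, 3791 higher and 3788 lower, and with library size only 7641, 2439 higher and 5202 lower.

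Basal cells were then compared with luminal cells to describe what set the 2 cell types apart, with the limit that each cell type was sequenced in its own lane. Averaged over the stages, Krt5 was higher in basal cells by 8.94 (SE 0.13), Actg2 by 8.91 (SE 0.16), Mylk by 8.32 (SE 0.14), the adhesion gene Cdh3 by 7.13 (SE 0.10) and the basement membrane collagen gene Col4a2 by 6.51 (SE 0.10). The luminal keratin gene Krt18 was lower in basal cells (-3.86, SE 0.10), as were the claudin gene Cldn7 (-5.72, SE 0.15), the kappa-casein gene Csn3 (-5.91, SE 0.15) and Scd1, a desaturase of fat synthesis (-4.33, SE 0.11). Tph1 (Entrez 21990), which starts serotonin synthesis, was lower in basal cells (-7.83, SE 0.20), the chemokine gene Cxcl15 lower (-8.14, SE 0.40) and the calcitonin gene Calca lower (-8.29, SE 0.62). The size of these values depends on the luminal share in basal counts. With luminal carry-over subtracted they were -4.48 for Krt18 and -4.95 for Scd1. Csn3 helps to define that share, and the subtraction left 0 counts of Cldn7, Tph1, Cxcl15 and Calca in the basal libraries of at least 1 stage, so no fold is given for them. Cxcl15 and Calca had 0 counts in lactating basal libraries before it too, which leaves the size of their change uncertain. Xkr4 and Ccdc153, with 0 counts in the 6 luminal libraries, were at least 470-fold and 402-fold higher in basal cells. Spock3, with 3 luminal counts, was 1100-fold higher (95% counting interval 377 to 5350) and Sez6l higher by 9.64 (SE 0.25), or by 10.73 without luminal pregnant replicate 1. Mcl1 was lower in basal cells by edgeR at -0.54 (SE 0.07, adjusted p = 1.46e-05).

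Basal identity had 16 of 16 genes higher, 16 over the list alone (median 6.90, camera adjusted p = 4.76e-07; adjusted p = 0.252 with an estimated correlation). The contractile list had 18 of 18 higher, 18 over the list alone (median 6.60, or 7.09 without a gene at 0 counts in a group; camera adjusted p = 2.15e-08; adjusted p = 0.290 with an estimated correlation). Basement membrane had 10 of 11 genes higher and 1, Lama5, lower (median 2.98, camera adjusted p = 0.000345; adjusted p = 0.270 with an estimated correlation), as over the list alone. Luminal identity had 11 of 11 lower, 11 over the list alone (median -1.94, camera adjusted p = 8.04e-05; adjusted p = 0.288 with an estimated correlation). All 13 milk protein genes were lower, 13 over the list alone (median -5.91, camera adjusted p = 5.53e-07; adjusted p = 0.270 with an estimated correlation). Tight junctions had 9 of 12 lower and 1 higher, as over the list alone (median -5.22, camera adjusted p = 0.000462; adjusted p = 0.300 with an estimated correlation). Cell cycle had 26 of 30 genes lower and 2 higher, as over the list alone (median -1.37, camera adjusted p = 0.000247; adjusted p = 0.639 with an estimated correlation). Oxidative phosphorylation had 24 of 25 lower and 1 higher, as over the list alone (median -0.73, camera adjusted p = 8.77e-06; adjusted p = 0.410 with an estimated correlation). Alveolar and luminal progenitor genes had 6 of 7 lower and 1 higher, as over the list alone (median -4.69, camera adjusted p = 0.0154; adjusted p = 0.371 with an estimated correlation).

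Markers of other cells were also higher on the basal side. Endothelial genes had 12 of 13 higher, 12 over the list alone (median 2.32, camera adjusted p = 0.00108; adjusted p = 0.558 with an estimated correlation). Fibroblast genes had 11 of 11 higher, 11 over the list alone (median 1.44, camera adjusted p = 0.00818; adjusted p = 0.501 with an estimated correlation). Adipocyte genes had 4 of 5 higher, 4 over the list alone (median 5.01, or 3.75 without genes at 0 counts in a group; camera adjusted p = 0.0314, and 0.0866 with library size only, where it was highest; adjusted p = 0.501 with an estimated correlation). Pericyte genes had 5 of 6 higher and 1 lower (median 3.51, camera adjusted p = 0.118). Hormone-sensing genes had 7 of 11 lower and 2 higher, as over the list alone (median -2.61, camera adjusted p = 0.0461; adjusted p = 0.270 with an estimated correlation). That call ended with luminal carry-over subtracted (adjusted p = 0.0927, median -2.74) and without basal virgin replicate 1 (0.0573), in a range from 0.0049. Dissociation genes had 13 of 17 higher and 2 lower (median 0.68, camera adjusted p = 0.114), and that list passed with the replicate block (adjusted p = 0.049, the lowest of the settings). The edgeR test called 13018 genes, 6622 higher and 6396 lower in basal cells, and with library size only 12797, 8429 higher and 4368 lower. At single stages it called 10023 genes in virgin (5037 higher, 4986 lower), 11155 in pregnant (5737 higher, 5418 lower) and 11914 in lactating mice (6253 higher, 5661 lower; with library size only 12736, 10207 higher and 2529 lower). Mcl1 was lower in basal cells by edgeR in virgin mice (-0.50, SE 0.13, adjusted p = 0.00379) and in pregnant mice (-0.92, SE 0.13, adjusted p = 2.66e-05). In lactating mice it was not called (-0.18, SE 0.13, edgeR adjusted p = 0.2), and it was higher in basal cells with library size only (0.81, adjusted p = 3.11e-05, the lowest of the settings).

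The last comparison tested whether the stage changes differed between the cell types, as the luminal minus the basal change. From pregnancy to lactation the cell cycle list parted most: 28 of 30 genes were higher on the luminal side, 30 over the list alone, with a median difference of 2.83 (camera adjusted p = 2.74e-12; adjusted p = 0.367 with an estimated correlation). The difference was 3.52 for Mki67 (SE 0.27), 3.96 for Ccna2 (SE 0.30) and 3.66 for Rrm2 (SE 0.27). Oxidative phosphorylation differed in 22 of 25 genes, 22 over the list alone (median 0.91, camera adjusted p = 2.41e-10; adjusted p = 0.270 with an estimated correlation). It was 1.39 for Cox5a (SE 0.14). The luminal change of Egf was higher than the basal one by 3.83 (SE 0.37). For the receptor genes Egfr and Erbb2 the difference was -1.38 (SE 0.20) and -0.99 (SE 0.16). For Mcl1 the difference was -0.74 (SE 0.18, edgeR adjusted p = 0.00593) from pregnancy to lactation and 0.42 (SE 0.18, edgeR adjusted p = 0.0921) from virgin to pregnancy. Cholesterol synthesis, higher in both cell types, rose more in luminal cells in 13 of 24 genes and less in 1, 15 and 1 over the list alone, with a median difference of 0.69 that was -0.12 with library size only (camera adjusted p = 0.000964; adjusted p = 0.468 with an estimated correlation). Tight junctions did not pass (8 of 12 higher, 2 lower, median 1.37, camera adjusted p = 0.0507, in a range of 0.0153 to 0.971 over the settings, 8 of which called it).

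Milk fat synthesis differed in 20 of 21 genes, 20 over the list alone (median 1.90, camera adjusted p = 3.08e-09; adjusted p = 0.238 with an estimated correlation). The difference was 3.46 for Slc25a1 (SE 0.19), 2.48 for the malic enzyme gene Me1 (SE 0.21) and 2.43 for Elovl5 (SE 0.15). ER protein folding differed in 12 of 18 genes and in 1 the other way, 14 and 1 over the list alone, with a median of 0.77 that was -0.04 with library size only (camera adjusted p = 0.000617; adjusted p = 0.501 with an estimated correlation). Xbp1, a regulator of the secretory apparatus, differed by 1.55 (SE 0.21). Basal identity had 6 of 16 genes lower on the luminal side, 6 over the list alone (median -0.63, camera adjusted p = 0.0259; adjusted p = 0.501 with an estimated correlation), a call lost with library size only (adjusted p = 0.089) and without luminal lactating replicate 2 (0.0648), in a range from 0.00642. The circadian clock had 9 of 16 genes higher on the luminal side and 1 lower, 11 and 2 over the list alone (median 1.10, camera adjusted p = 0.0165; adjusted p = 0.367 with an estimated correlation). Interferon response had 1 gene higher and 1 lower of 15, and 0 and 1 over the list alone, with a median of -0.03, a mean of 0.09 and a camera test pointing up (adjusted p = 0.912). By edgeR 5787 genes differed, 2918 higher and 2869 lower on the luminal side, and with library size only 8933, 1012 higher and 7921 lower. From virgin to pregnancy 4908 differed, 2242 higher and 2666 lower, and with library size only 5622, 1008 higher and 4614 lower.

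The changes of the 2 cell types were related across genes, which are not independent replicates. Their Pearson correlation was 0.324 from virgin to pregnancy, 0.164 from pregnancy to lactation and 0.225 from virgin to lactation, and the Spearman correlations were 0.270, 0.156 and 0.166. The covariances were 0.265, 0.125 and 0.306, of which 0.016, 0.012 and 0.009 are expected from shared mice alone, if same-numbered libraries share a mouse. From virgin to pregnancy 963 genes rose in both cell types and 996 fell in both, where independent calls would give 544.1 and 554.8. In the step to lactation 780 rose in both and 1159 fell in both, against 593.8 and 684.8 for independent calls. Genes called in opposite directions numbered 552 (higher in luminal, lower in basal cells) and 540 (the reverse) in that step, against 658 and 618. With luminal carry-over subtracted the correlation was 0.160 from virgin to pregnancy and 0.099 from virgin to lactation.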

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

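Results are listed here because the luminal and the basal change differed by the edgeR or camera test of that difference. From virgin to pregnancy 4908 genes differed and from pregnancy to lactation 5787. Differences are luminal minus basal log2 changes, as medians for lists.

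From virgin to pregnancy the difference was 1.14 for milk fat synthesis and 1.17 for milk ion and nutrient transport. It was 0.75 for ER protein folding, -1.96 for hormone-sensing luminal genes, -0.81 for the contractile apparatus and -0.68 for the circadian clock. In that order the camera adjusted p was 4.42e-06, 8.04e-05, 0.000606, 4.42e-05, 0.00617 and 0.0473, and with an estimated correlation it was 0.27, 0.219, 0.501, 0.219, 0.572 and 0.46.

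From pregnancy to lactation it was 2.22 for milk proteins, 1.90 for milk fat synthesis, 2.06 for milk fat globule secretion, 0.53 for lactose synthesis and 1.72 for milk ion and nutrient transport. It was 0.69 for cholesterol synthesis, 0.77 for ER protein folding, 2.83 for the cell cycle, 0.91 for oxidative phosphorylation and 1.53 for fibroblast markers. It was 1.10 for the circadian clock, -0.63 for basal identity and -0.64 for the contractile apparatus (-0.58 without a gene at 0 counts in a group). With library size only the medians of lactose synthesis, cholesterol synthesis and ER protein folding in that step were -0.28, -0.12 and -0.04.

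For these 13 lists, in the order given, the camera adjusted p was 8.86e-07, 3.08e-09, 0.000472, 0.0068, 0.000581, 0.000964, 0.000617, 2.74e-12, 2.41e-10, 0.0146, 0.0165, 0.0259 and 0.0343. With an estimated correlation it was 0.27, 0.238, 0.288, 0.252, 0.224, 0.468, 0.501, 0.367, 0.27, 0.523, 0.367, 0.501 and 0.661, so none was called in that way. The calls of lactose synthesis (0.0803), basal identity (0.089) and the contractile apparatus (0.144) were lost with library size only, and that of basal identity also without luminal lactating replicate 2 (0.0648). That of the contractile apparatus was also lost with luminal carry-over subtracted (0.0551, median -0.61) and without luminal pregnant replicate 2 (0.0534), luminal lactating replicate 1 (0.0715), basal pregnant replicate 1 (0.14) or basal lactating replicate 1 (0.0658). Its range started at 0.0102.

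Among named genes with counts in every group, the largest positive differences in the step to lactation were those of Pcp4 (9.18, SE 0.74), Apod (7.44, SE 0.49) and Sv2c (6.76, SE 1.45). Pcp4, whose exons overlap another gene by 23.7% and which is uncertain, gave 10.35 and 8.59 without luminal pregnant replicates 1 and 2. Sv2c rested on 1 basal count in lactation, so the size of its difference is uncertain. It gave 7.37 and 5.85 without luminal lactating replicates 1 and 2, and 5.89 and 9.14 without basal lactating replicates 1 and 2. Creb5 differed by -5.62 (SE 0.27), Tnni2 by -5.57 (SE 1.13; -6.24 without basal pregnant replicate 2) and H19 by -9.51 (SE 0.81), over 3 luminal counts in lactation, so the size is uncertain. H19 gave -14.03 and -8.51 without luminal lactating replicates 1 and 2. Genes with a group at 0 counts have no stable fold, so their edgeR adjusted p is given: 0.00204 for Fer1l4, 0.0243 for Cxcl17, 0.0147 for Pcyt1b and 0.0182 for Tmem154. Cxcl17 was not called without basal pregnant replicate 1 (0.299), basal lactating replicates 1 or 2 (0.0695 each) or with luminal carry-over subtracted (0.0778). Without luminal pregnant replicate 2 and luminal lactating replicates 1 and 2, in that order, the adjusted p was 0.0719, 0.055 and 0.0566 for Pcyt1b and 0.075, 0.0676 and 0.07 for Tmem154.

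The luminal change exceeded the basal one for Ccna2 (3.96), Egf (3.83), Rrm2 (3.66), Mki67 (3.52), Slc25a1 (3.46), Slc34a2 (3.28), Slc30a2 (3.03) and Insig1 (2.89). It did so for Btn1a1 (2.81), Me1 (2.48), Elovl5 (2.43), Muc1 (2.42), Rab18 (2.06), Tm7sf2 (1.92), Pmvk (1.85) and Slc7a5 (1.72). It did so also for Xbp1 (1.55) and Cox5a (1.39), and, as uncertain genes with exon overlaps of 63.5% and 43.8%, for Trf (2.59) and Atp5o (1.65). Cel (2.24) and Wfdc18 (2.23) were not called with luminal carry-over subtracted (adjusted p = 0.44 and 0.27). Their differences were then 1.47 and 2.98, each with an SE above 1 (0.23 and 0.29 before), so that of Wfdc18 did not shrink and its call ended with the larger SE. Asns (1.16), Ndufs1 (1.15) and Pdia6 (0.97) were not called with library size only (adjusted p = 0.102, 0.0641 and 0.461). With luminal carry-over subtracted the differences of Slc34a2, Slc30a2, Btn1a1 and Trf kept their call, but 6.4%, 31.2%, 0% and 7.2% of their basal counts in lactation were left, so their size there is not given. For Muc1 27.2% of these counts were left, so the size of its difference is uncertain too. The luminal change was the lower one for Mcl1 (-0.74), Erbb2 (-0.99) and Egfr (-1.38).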

How the results depend on the processing

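With 1 library left out, the genes called ranged from 5673 to 7531 in luminal pregnant against virgin, 5901 to 7824 in luminal lactating against pregnant and 8043 to 9757 in luminal lactating against virgin cells. In basal cells the ranges were 3009 to 4996, 2735 to 5424 and 5710 to 7753. Between cell types they were 8620 to 10292, 10009 to 11318, 10925 to 12082 and, averaged, 12857 to 13074, and for the differences 3709 to 4649 and 4573 to 5924. The moves past 1.5-fold were 3009 without basal pregnant replicate 2 for basal pregnant against virgin, and 2735 without basal pregnant replicate 1 and 2806 without basal lactating replicate 2 for basal lactating against pregnant cells. The cause was not tested. Of 3514 values of named genes 143 lost their call without 1 library, and of 2010 values of lists 21 lost and 32 gained one. A lone library was assumed to vary like the other groups.

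With library size only 8933 genes differed in the step to lactation, against 5787. That scaling turned the sign of Cd68 in luminal pregnant against virgin cells (-0.10), of Ndufb8 in luminal lactating against pregnant cells (-0.17) and of Mcl1 between cell types in lactating mice (0.81), which follows from its shift of all genes. Of the other gene values 12 lost and 1 gained a call, and of 168 list values 11 lost and 8 gained one.

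With luminal carry-over subtracted, chosen after seeing the data, Btn1a1 (-0.37) and Glycam1 (-1.55) in basal pregnant against virgin cells and Cidea (-6.88) in basal lactating against pregnant cells turned sign, which follows from removing most of their basal counts. The correlation of the luminal and basal changes moved to 0.160 from virgin to pregnancy and 0.099 from virgin to lactation. Further, 19 gene and 10 list calls were lost. The subtraction is no test of the 8 milk genes that define the share, Glycam1 among them, nor of the milk protein list. Some lost list calls kept their median, as for tight junctions in luminal pregnant against virgin cells (0.43), the BCL2 family (-0.68) and EGF ligands and receptors (-0.97) in luminal lactating against pregnant cells.

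In the comparisons of stages the replicate block was a single term for the replicate number, shared by all stages. It therefore tied mice of different stages and did not pair the 2 cell types of a mouse. In the other comparisons it was a term per stage, which pairs same-numbered libraries of the 2 cell types. With the block, Isg15 in basal pregnant against virgin cells (edgeR adjusted p = 0.0512) and the BCL2 family in luminal lactating against pregnant cells (camera adjusted p = 0.052), both comparisons of stages, lost their call. The dissociation list between cell types gained one (0.049). Of the 293 named gene values and 168 list values no other call changed, but the counts of called genes moved, for the differences from 4908 to 5692 and from 5787 to 6483.

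Calls of named genes were lost in 10 of 293 cases with DESeq2, 9 with limma voom, 6 with RLE normalization, 4 without a filter, 3 with abundant genes left out of library sizes and 5 of 198 with 1 cell type alone. The stricter filter kept 277 of 277, and 16 named values had no value in some setting because the gene was not tested. Of the 168 list values, which cover the comparisons with named genes, 72 were called. All 72 were lost with an estimated correlation, and fry lost 4 and gained 44. Depth limits genes of a few counts, so fitted changes given for them are uncertain in size.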

Other observations

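The results below are weighed against explanations other than a change of expression. The tests of own expression of milk genes by basal cells and of misassigned indices, and that of scaling for the luminal rise alone, were written only after the result was seen, and the subtraction of luminal carry-over was chosen after seeing the data.

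Milk transcripts stood higher in basal libraries of pregnant and lactating mice than of virgin mice. Carry-over of luminal RNA or cells may explain it: at most 0.27% of abundant luminal genes lay below 0.5 of the milk ratio in any of the 4 basal libraries. That test counted all abundant luminal genes, also those that basal cells express. Such genes lie above this ratio with or without carry-over, so the low percentage is weak evidence for it. Misassigned indices within the lane are argued against, since the highest milk share among the basal lane's libraries was 0.759%, although other libraries of that lane are unknown. Own expression of milk genes by basal cells could not be told apart, with an SD of up to 0.49 of the log2 ratio over 8 milk genes. Whether basal cells make any of these transcripts stays open.

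Cell cycle genes rose in luminal and fell in basal cells from pregnancy to lactation. Scaling for library composition is unlikely to explain the difference between the cell types, since the lowest median difference over 3 scaling alternatives was 2.01. For the luminal rise alone scaling could not be told apart: the lowest luminal median over these alternatives was 0.19, so a luminal rise against the whole RNA content of the cell stays open. Luminal carry-over is argued against by the basal median of -1.95 after the luminal share was subtracted. A changed mix of cells within each sort was not tested and stays open.

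Oxidative phosphorylation genes rose in both cell types in pregnancy. A trend with gene length and abundance is unlikely to explain it, since the list's median lay at percentile 99.47 or above of 10000 matched random lists. In luminal cells the median was 0.47 against -0.04 to 0.39 for random lists, and in basal cells 0.51 against -0.03 to 0.28. The luminal median turned to -0.03 with library size only, so a rise against the whole RNA content of the cell stays open.

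The count of genes between cell types was also compared with other splits of the libraries. Of 100 splits within stages 1, the real one, called 13018 genes, and the highest other called 10388. Every other split put libraries of both sorted cell types on the same side. The real split was therefore likely beforehand to call the most genes, and no conclusion on chance is drawn from its rank. With same-numbered libraries of a stage assumed to share a mouse, 31 splits, the real one included, parted as many mice (6). The highest other was among them and kept 8 of 12 libraries on their cell type side. The median of the others was 0 genes. Lane and cell type coincide in all of these, and the effect of the lane stays open.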
